A study of Danio rerio with 18 samples.

How the data were processed

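RNA sequencing was done on zebrafish mature eggs and FG follicles, with 5 wild-type and 5 sinhcaf mutant egg libraries and 4 wild-type and 4 mutant FG follicle libraries, 18 in all. Per the labels, the tissue was ovary, a library held the eggs or follicles of a single female, RNA integrity was at least 7, and libraries were made with the TruSeq Stranded mRNA kit. The labels do not spell out FG, and the word is used as they give it.

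The deposited table holds FPKM values, which scale fragments by gene model length and mapped fragments, for 25432 Ensembl genes in 18 library columns, and every library column was used. The authors made the values with a chain that names Trimmomatic, HISAT2, Cufflinks and HTSeq and the build GRCz11, per the submitters' processing notes. Those notes give no versions, no order and no roles, so which tool gave the FPKM values, which annotation was used, how reads shared by similar genes were counted and whether strand was used are not stated. The values are fractional, and their sums differ between libraries, as FPKM sums do. No table of read counts was used, and whole counts could not be recovered from the steps between low values, so depth is unknown and precision rests on the spread between fish alone. Symbols and descriptions are those of the table. Some symbols look changed by spreadsheet software, and 479 names are used more than once.

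Values were taken as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 4 libraries were tested, 10547 in all. A linear model with 4 group means was fitted with limma 3.58.1 (lmFit, eBayes with a trend in the prior variance) in R 4.3.3, with the data.table package (1.17.8). The model leaves 14 residual degrees of freedom. From it came 5 contrasts: mutant against wild type in eggs and in FG follicles, the difference of both, and eggs against FG follicles in each genotype. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05. Log2 changes, their standard errors and the folds they give are on this scale, so that genes near 0 FPKM have changes drawn towards 0.

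The level of sinhcaf, 4 library measures per stage and mean scores of 6 marker lists of other cell types per stage were compared with two-sided exact permutation tests of the difference in means, which cannot go below 0.00794 for 5 against 5 or 0.0286 for 4 against 4. The overlap of calls between stages was tested with Fisher's exact test, per direction. No library is shared between the egg and the FG follicle comparison.

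The comparisons, the gene lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. There were 30 gene lists: the SIN3 complex, 8 microtubule lists, egg coat, oocyte and maternal genes, meiosis, hormone receptors and steroid synthesis, 6 lists of other cell types, histones, chromatin repressors, Wnt, ribosomal, mitochondrial, p53, heat shock and calcium genes. Of their members, 827 matched a symbol of the table, 23 matched through a synonym, and 73 had no match. The 26 lists with at least 5 tested genes were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over lists within a contrast, beside counts of called members over all genes and over the list alone. Camera with an estimated correlation and fry were run as alternatives. Some genes stand on more than 1 list.

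Genes were named by rule. For each genotype comparison these are the 10 largest rises and the 10 largest falls among called genes with a mean FPKM of at least 1 in either group, a proper symbol and groups that do not overlap. For every other contrast they are the 5 largest each way. Up to 4 called members of each list follow. Names shared by several tested genes or marked as copies of many were also left out. The text gives 58 of 98 genes so named in eggs and 67 of 113 in FG follicles, by a narrowing made after the data were seen: all of the largest changes, all named members of called lists, 2 members of each microtubule list and 1 of each other list. A gene that these rules select is not reported here and was not replaced.

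The table has no coordinates, and the only annotation at hand is of the assembly GRCz12tu, a build other than that of the table. It was used for synonyms and for which genes neighbour each other, with 9631 tested genes placed, and no coordinates are printed.

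Steps chosen after the data were seen are the pooled test of all microtubule lists, Gene Ontology terms from the table's annotation (Fisher's exact test, 770 terms of 10 to 500 genes among 9254 annotated genes), counts of neighbouring genes, exact permutation tests on the mean of a list per library (zona pellucida in FG follicles, ribosomal proteins in eggs), separate fits of egg libraries 1 to 3 and of 4 and 5, a block nested in stage, and mutant FG follicle libraries 1 and 3 averaged, since those correlated best (r = 0.997 across genes) although they differ by more than counting allows. Settings chosen beforehand were pseudocounts of 0.1 and 0.5, no filter and an FPKM minimum of 5, median-of-ratios scaling, quantile normalization, TPM with and without mitochondrially encoded genes, other variance models, a replicate block, a minimum log2 change of 1 and leaving out each library in turn.

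Whether replicate numbers pair the libraries was checked from the data, since the labels do not say so. Deviations from the group means of same-numbered wild-type and mutant egg libraries correlated at 0.11 to 0.45 in all 5 pairs, and 4 of 10 egg libraries correlated best with their own number. In FG follicles the 4 pairs gave -0.12 to -0.02. Blocked values are therefore among the alternatives.

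The chain of tests was tested on simulated data of the same genes and groups, with 67 genes changed by each of the smaller sizes and 66 by the largest. In eggs 16.4% of genes changed by 0.5 on the log2 scale were recovered, 86.6% at 1 and 86.4% at 2, with 8 false calls of 134. In FG follicles these were 28.4%, 77.6% and 93.9%, with 16 false calls of 149. The simulated noise was normal and independent between genes and libraries, and it held no split of the egg libraries by number. The simulation therefore checks that the steps run as meant and does not measure the share of false calls in the real data. Outlying libraries were kept.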

Results

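Messenger RNA was sequenced from mature eggs and from FG follicles of zebrafish ovaries, in wild-type fish and in fish mutant for sinhcaf. The sinhcaf product is a subunit of the SIN3 and histone deacetylase co-repressor complex. There were 5 wild-type and 5 mutant egg libraries, and 4 wild-type and 4 mutant FG follicle libraries. Per the labels, a library was made from the pooled eggs or follicles of a single female, so a replicate is taken to be a fish. The values are FPKM for 25432 genes. The values carry no read counts, so the depth of the libraries is unknown and no counting interval can be given. Summed FPKM ran from 375178 to 404150 in wild-type eggs and from 376795 to 464199 in mutant eggs. It ran from 309889 to 340960 in wild-type FG follicles and from 287120 to 305601 in mutant FG follicles. An egg library held 7292 ± 378 genes at an FPKM of at least 1 in wild type (SD, n = 5) and 7461 ± 447 in mutants (SD, n = 5). An FG follicle library held 9807 ± 68.9 such genes in wild type (SD, n = 4) and 9930 ± 128 in mutants (SD, n = 4). The first principal component, with 83.5% of the variance, parted eggs from follicles, and the next, with 6.2%, parted mutant from wild-type libraries at both stages.

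The targeted gene was low in all libraries and lower in mutants at both stages. In eggs, sinhcaf (ENSDARG00000032653) stood at 0.248 ± 0.0651 FPKM in mutants and 0.726 ± 0.509 FPKM in wild type (SD, n = 5 each). All 5 mutant egg libraries lay below all 5 wild-type ones, a log2 difference of -0.42 (two-sided exact permutation p = 0.00794, the smallest possible), while the limma adjusted p was 0.21. In FG follicles the level was 0.607 ± 0.315 FPKM in mutants and 2.14 ± 1.12 FPKM in wild type (SD, n = 4 each), a log2 difference of -0.90. The exact permutation p there was 0.0857, where the smallest possible is 0.0286, and the limma adjusted p was 0.0115. Wild-type FG follicle library 4, at 0.615 FPKM, lay inside the mutant range of 0.359 to 1.04 FPKM. Without that library the difference was -1.19 with an exact permutation p of 0.0286. Without wild-type egg library 4 the egg difference was -0.27, with the groups still apart (exact permutation p = 0.00794). At such low FPKM the size of the difference depends on the pseudocount and the scaling, and over the alternative settings it ran from -1.08 to -0.27 in eggs and from -1.56 to -0.70 in FG follicles, lower in mutants in all of them.

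Transcripts of the mitochondrial genome took a larger share of summed FPKM in mutant eggs and a smaller one in mutant FG follicles. In eggs the share was 43.4% ± 5.80 in mutants and 35.5% ± 1.99 in wild type (SD, n = 5 each; two-sided exact permutation p = 0.0238, adjusted over 8 library tests 0.0572). In FG follicles it was 10.5% ± 3.05 in mutants and 15.3% ± 1.65 in wild type (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0572). Cytosolic ribosomal protein genes, whose products build the cytoplasmic ribosome, took 2.68% ± 0.285 of summed FPKM in mutant eggs and 4.02% ± 0.473 in wild-type eggs (SD, n = 5 each; exact permutation p = 0.00794, adjusted 0.0572). Their share in FG follicles was 3.37% ± 0.152 in mutants and 3.68% ± 0.438 in wild type (SD, n = 4 each; exact permutation p = 0.286, adjusted 0.327). Summed FPKM in FG follicles differed by -31700 (exact permutation p = 0.0286, adjusted 0.0572). The same sum differed by 29150 in eggs (0.103, adjusted 0.165). The number of genes at an FPKM of at least 1 did not part the genotypes in eggs (0.5, adjusted 0.5) or in FG follicles (0.171, adjusted 0.228). None of these tests passed the correction, and FPKM values of all genes depend on these shares.

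**Figure D1:**
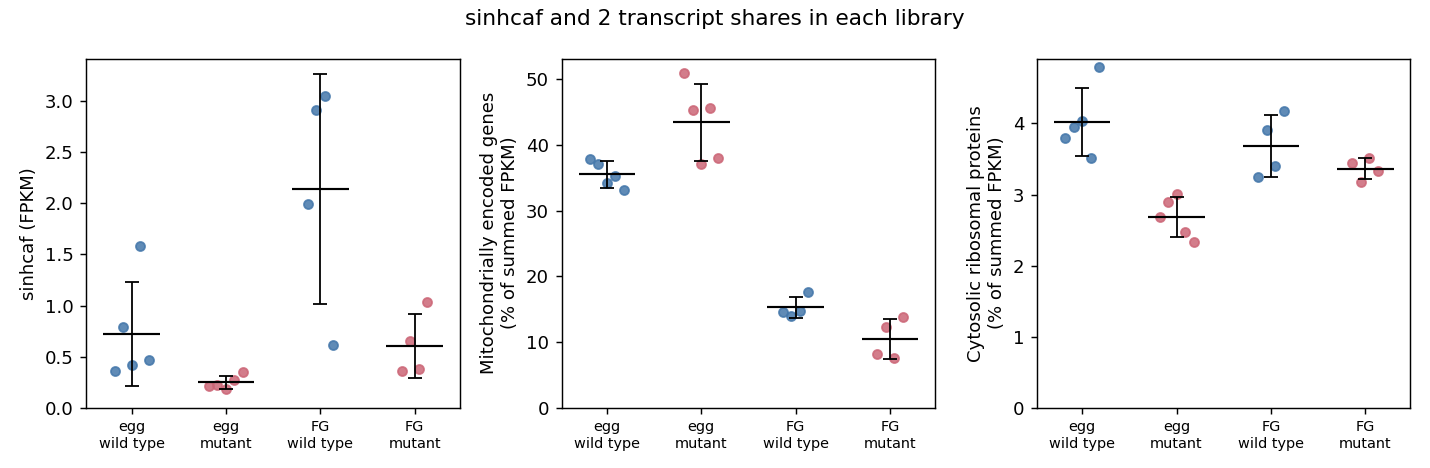
Each dot is a library and each line a group mean, for sinhcaf in FPKM, for mitochondrially encoded genes and for cytosolic ribosomal protein genes in percent of summed FPKM, by stage and genotype. Mutant eggs lie at 37.1 to 51% mitochondrial transcripts against 33.1 to 37.9% in wild-type eggs, and their ribosomal protein share of 2.33 to 3.01% lies below the wild-type range of 3.52 to 4.79%.

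The comparison of mature eggs asked which transcripts differ in the eggs of mutant females. By camera at its preset correlation, 3 lists passed: ribosomal protein genes, lower in mutant eggs (36 of 80 called), and higher zona pellucida genes, which encode the glycoproteins of the egg coat (4 of 14), and genes of the mitochondrial genome (1 of 13). None passed with an estimated correlation (adjusted p = 0.85 each), and 43 of 100 splits of the libraries, the real one included, called as many lists. A few genes were nearly missing from mutant eggs. The transcript of spsb1, an adaptor of a ubiquitin ligase, fell from 219 ± 60 to 1.48 ± 0.574 FPKM, and that of spns1, a lysosomal lipid transporter, from 84.5 ± 6.26 to 0.896 ± 0.22 FPKM (SD, n = 5 each). In the other direction, hdac3, a histone deacetylase of other co-repressor complexes, rose from 3.18 ± 0.957 to 26.5 ± 5.49 FPKM (SD, n = 5 each).

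Among 10547 genes tested with limma, 1588 passed an adjusted p of 0.05 in eggs, 775 higher and 813 lower in mutants. Of these, 184 were higher and 225 lower by at least 1 on the log2 scale. The groups of libraries did not overlap in 1168 of the genes tested, where chance gives 0.794% of genes. The share of higher genes among calls was 48.8%, and it moved to 38.8% with median-of-ratios scaling, 34.4% with TPM and 65.3% with TPM without mitochondrial genes. The last of these shifted the median gene from 0.04 to 0.14 on the log2 scale. The largest falls beside spsb1 (log2 -6.46, SE 0.21, adjusted p = 6.02e-14) and spns1 (-5.50, SE 0.12, adjusted p = 6.61e-16) included sec11a, the catalytic part of signal peptidase, at -4.76. The DNA repair gene fancg followed at -4.67, the tRNA methyltransferase gene mettl2a at -4.54, rnf41 at -4.00 and the urate pathway gene urahb at -4.00. Then came dpm1 at -3.46 and pigl at -3.29, both of glycolipid anchor and sugar donor synthesis, and fgd4b at -3.28. The largest rise was that of lsm12a, from 12.7 ± 26.3 to 120 ± 36.3 FPKM (log2 4.97, SE 0.86, adjusted p = 0.000498). Wild-type egg library 5 held 59.7 FPKM of lsm12a and the other wild-type egg libraries at most 1.66. The nucleotide synthesis gene prps1b rose by 3.80, rhogd by 2.95, kyat3 by 2.80, hdac3 by 2.73 and gpx8 by 2.52. Further rises were those of the endocytic recycling gene ehd1a (2.46), rnf141 (2.42) and the mitochondrial transporter gene abcb10 (2.37). The gene lrrc30a was listed at 0 in all wild-type libraries and at 5.52 ± 3.18 FPKM in mutant eggs, so no fold is given.

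In the list of cytosolic ribosomal proteins, 36 of 80 tested members fell in mutant eggs and none rose (0 higher and 47 lower adjusted over the list alone). The median change was -0.49 (camera adjusted p = 3.18e-14; adjusted p = 0.85 with an estimated correlation). Examples were rpl19, from 427 ± 70.7 to 226 ± 56.6 FPKM, rps8a, from 153 ± 27.1 to 82.1 ± 14.9 FPKM, rpsa, from 116 ± 26.1 to 62.7 ± 15.8 FPKM, and rpl36a, from 20.9 ± 10.6 to 8.91 ± 2.12 FPKM (SD, n = 5 each). Of 14 zona pellucida genes, 4 rose and none fell (6 and 0 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.0299; adjusted p = 0.85 with an estimated correlation). They were zp2.5 (log2 1.67), zp2.2 (1.26), zp3b (0.87) and zp2.1 (0.69), all far below their follicle levels in eggs of both genotypes, and the zp2.1 call was lost in 10 of 34 alternative settings, the replicate block among them. Among 13 mitochondrially encoded genes, mt-nd5 rose from 3190 ± 213 to 4880 ± 1070 FPKM and no gene fell (4 and 0 adjusted over the list alone). That list had a median of 0.39 (camera adjusted p = 0.0136; adjusted p = 0.85 with an estimated correlation). Other splits of the egg libraries gave as many called lists in 43 of 100 cases, the real split included, so these list calls are not set apart from other groupings. The zona pellucida call ended with median-of-ratios scaling, with quantile normalization, with TPM without mitochondrial genes, with array weights, in egg libraries 1 to 3 alone and without mutant egg library 2 or wild-type egg library 4 or 5. The mitochondrial call ended with median-of-ratios scaling, with quantile normalization (where mt-nd5 also lost its call, as it did in 6 of 33 alternative settings in all), in egg libraries 1 to 3 and in 4 and 5 alone and without mutant egg library 1 or wild-type egg library 4 or 5. By fry, which tests a list on its own, neither passed (adjusted p = 0.0702 and 0.175), while ribosomal proteins did (0.0302).

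The lists of microtubule genes were fixed with the series title in view, which says that such genes are lower in mutants, so their direction is not independent evidence. In eggs, tubg1, the gamma-tubulin that nucleates microtubules, fell from 19.3 ± 2.34 to 11.7 ± 1.4 FPKM, and tuba8l2 from 4.95 ± 0.653 to 1.98 ± 1.48 FPKM (SD, n = 5 each). The other 9 of 11 tubulins did not pass the test (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.303). The gene map7d3, whose product binds microtubules, fell from 1.48 ± 0.369 to 0.102 ± 0.0454 FPKM. It was 1 of the 4 microtubule-associated genes of 38 that fell, against 1 that rose. The median of that list was 0.06 while its mean (-0.05) and test pointed down (camera adjusted p = 0.599). Among 24 kinesins and their partners, kif1bp fell (-1.11) and kif13bb rose (0.55; camera adjusted p = 0.303). The dynein light chain gene dynll1 rose (0.78), as did dctn5 (0.66) of dynactin, the cofactor of dynein, with 2 of 14 dynein and dynactin genes higher and 1 lower (camera adjusted p = 0.441). Spindle genes went both ways, with 3 of 40 higher, among them hmmr (0.58) and the checkpoint kinase gene bub1ba (0.55), and 3 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.913). On the centrosome list 1 of 49 genes rose, cep131 (0.89), and 3 fell, among them azi2 (-0.66), whose own tie to the centrosome was not checked. Adjusted over the list alone, 1 rose and 0 fell (camera adjusted p = 0.991). In the intraflagellar transport list, ift80 (-0.80) and ift57 (-0.40) fell and 1 of 16 rose (camera adjusted p = 0.913). The axonemal list had only 2 tested genes, of which dnal1 fell (-0.86). The call of ift57 was lost in 8 of 34 alternative settings, those of azi2 and kif13bb in 6 and those of dynll1 and dnal1 in 5. Over all 193 tested members of these lists, 17 were lower in mutant eggs (8.8%, against 7.7% of other genes; Fisher's exact p = 0.584) and 9 were higher (4.7%, against 7.4%; 0.165).

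Single members of further lists moved in eggs while the lists did not pass the test. The SIN3 complex genes held 2 higher and 0 lower of 24, with brms1la at 4.18 ± 2.12 and 8.70 ± 1.45 FPKM in wild type and mutants (camera adjusted p = 0.456). The maternal gene zar1l fell from 184 ± 75.9 to 72.0 ± 28.2 FPKM, in a list of 32 oocyte-secreted and germ plasm genes with 1 higher and 3 lower (0.442). The splicing helicase gene dhx16 fell (-0.97) among 43 maternal-effect genes with 2 higher and 4 lower (0.442). A subunit gene of the anaphase-promoting complex, cdc26, fell from 5.74 ± 1.27 to 0.0909 ± 0.0845 FPKM, among 44 meiosis and M-phase genes with 2 higher and 6 lower (0.428). The p53 target ccng1 fell from 120 ± 61.9 to 20.5 ± 4.65 FPKM (1 higher and 1 lower of 25; 0.665), and the mitochondrial chaperone gene hspa9 rose from 1.32 ± 0.242 to 5.88 ± 0.966 FPKM (2 higher and 5 lower of 34 heat shock genes; 0.442). The progesterone receptor component gene pgrmc1 fell (-0.77; 0 higher and 2 lower of 21 hormone receptor genes; 0.456), as did h2af1al (-0.82; 2 higher and 3 lower of 30 histones; 0.954) and calm3a (-0.82; 0 higher and 3 lower of 32 calcium signalling genes; 0.442). The developmental signal gene wnt8a rose (0.71, a call lost in 12 of 34 alternative settings; 1 higher and 1 lower of 29 Wnt genes; 0.668), as did NDUFAF8 (0.94; 2 higher and 11 lower of 95 nuclear respiratory chain genes; 0.442). Chromatin repressors, with hdac3 among them, held 2 higher and 5 lower of 49 (0.303). Adjusted over the list alone the counts were 3 higher and 5 lower for maternal-effect genes, 0 and 1 for hormone receptors, 2 and 4 for chromatin repressors and 0 and 1 for Wnt genes, where wnt8a was not called.

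Marker lists of other ovarian cell types gave low scores in eggs, in mean log2(FPKM + 1) per list. The granulosa score was 0.298 ± 0.0440 in mutants and 0.201 ± 0.01 in wild type, and the leukocyte score 0.454 ± 0.0240 and 0.348 ± 0.0190 (SD, n = 5 each). The theca and stromal score was lower in mutants, by -0.081. For each of these 3 scores the exact permutation p was 0.00794, 0.0318 when adjusted over 12 scores, and all 5 mutant libraries lay on one side of all wild-type ones. A few members carry these differences, as cxcr4b makes 52.2% of the summed leukocyte difference and it and one more gene 84.8%, fn1a 45.9% of the theca and stromal one and cyp11a1 39% of the granulosa one. The erythrocyte score differed by 0.032 (exact permutation p = 0.0317, adjusted 0.0951), the endothelial score by 0.006 (0.675, adjusted 0.9) and the liver score by 0 (0.968, adjusted 1). Called members were cyp11a1, the first enzyme of steroid synthesis, which rose from 30.8 ± 4.01 to 85.8 ± 42.6 FPKM and is on the granulosa and the steroidogenesis lists, the chemokine receptor gene cxcr4b, from 1.15 ± 0.378 to 8.34 ± 2.5 FPKM, fn1a (-1) and cldn5b (0.53, a call lost in 9 of 34 alternative settings). By camera none of the lists of this kind with at least 5 tested genes passed in eggs: granulosa (1 higher and 0 lower of 14; adjusted p = 0.599), steroidogenesis (1 and 0 of 18; 0.599), theca and stromal (0 and 2 of 10; 0.4) and leukocyte (2 and 0 of 6; 0.303). Neither erythrocyte (0 of 4) nor liver markers (0 of 1) held a called gene, and endothelial markers held 1 of 2.

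The comparison of FG follicles asked the same of the follicle samples. By camera at its preset correlation, 6 lists passed. Called higher in mutants were 8 of 14 zona pellucida genes, 6 of 14 granulosa markers and 6 of 18 steroid synthesis genes (2 lower), and called lower were 6 of 11 tubulins, 9 of 13 mitochondrially encoded genes and 10 of 80 ribosomal protein genes (2 higher). None of the 6 lists passed with an estimated correlation (adjusted p = 0.563 to 0.723), and 12 of 35 splits of the libraries, the real one included, called as many. The egg coat gene zp2.5 rose from 19.0 ± 11.3 to 155 ± 49.7 FPKM, and mt2, a metallothionein that binds metal ions, from 13.1 ± 5.88 to 183 ± 24.5 FPKM (SD, n = 4 each). The transcript of mrpl1, a protein of the mitochondrial ribosome, fell from 32.8 ± 4.89 to 0.439 ± 0.252 FPKM, and that of spsb1 from 48.2 ± 11.4 to 0.176 ± 0.0442 FPKM.

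By limma 2475 genes passed the threshold in FG follicles, 1061 higher and 1414 lower in mutants, of which 262 and 339 changed by at least 1 on the log2 scale. The groups did not overlap in 3055 of the tested genes, where chance gives 2.86% of genes. The share of higher genes was 42.9%, and 59.9% with TPM, which moved the median gene from -0.05 to 0.08. Largest were the rises of mt2 (log2 3.79, SE 0.29, adjusted p = 1.47e-08), zp2.5 (3.19, SE 0.45, adjusted p = 4.68e-05), prps1b (2.93), gpx8 (2.63), kyat3 (2.61), gemin4 (2.37), the transcription factor gene sox5 (2.33), hdac3 (2.25) and sde2 (2.25). For sde2, wild-type FG follicle library 4 stood at 6.81 FPKM and the other wild-type ones at most at 0.466. Again lrrc30a was listed at 0 in wild type, with 4.10 ± 0.871 FPKM in mutants. Largest were the falls of spsb1 (-5.35, SE 0.23, adjusted p = 3.31e-12), sec11a (-4.81), mettl2a (-4.59), mrpl1 (-4.56), kansl2 of a histone acetyltransferase complex (-4.33), mrps22 of the mitochondrial ribosome (-4.14), fgd4b (-3.82), the receptor gene gpr157 (-3.80) and fancg (-3.77). Mutant FG follicle library 4 held 23.5 FPKM of kansl2 and the other mutant ones at most 0.49. The stress-response gene nupr1b was listed at 0 in mutants and at 24.5 ± 7.47 FPKM in wild type.

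Tubulins, the subunits of microtubules, fell in mutant FG follicles in 6 of 11 cases, with none higher (0 higher and 8 lower adjusted over the list alone). The median was -0.48 (camera adjusted p = 0.0308; adjusted p = 0.563 with an estimated correlation). The beta-tubulin gene tubb5 fell from 10.1 ± 5.82 to 1.88 ± 1.11 FPKM, and the alpha-tubulin genes tuba8l2 from 19.5 ± 4.5 to 7.66 ± 3.6, tuba1b from 5.95 ± 3.02 to 2.48 ± 1.18 and tuba1c from 2.11 ± 0.864 to 0.843 ± 0.224 FPKM (SD, n = 4 each). As in eggs, the microtubule lists were chosen with the title in view and are not independent evidence of direction. Spindle and checkpoint genes held 12 lower and 2 higher of 40 (the same adjusted over the list alone), with the kinetochore genes dsn1, from 17.7 ± 4.56 to 7.58 ± 3.38 FPKM, and ndc80, from 79.6 ± 9.83 to 46.2 ± 1.7 FPKM. The centrosome list held 13 lower and 3 higher of 49 (16 and 3 adjusted over the list alone), with the scaffold gene pcnt (-0.77) and azi2 (-0.78), whose tie to the centrosome was not checked. Microtubule-associated genes held 8 lower and 4 higher of 38 (9 and 4 adjusted over the list alone), with map7d3, from 2.93 ± 0.362 to 0.214 ± 0.0331 FPKM. Kinesins held 5 lower and 0 higher of 24 (7 and 0 adjusted over the list alone), with kif26ab (-1.18) and kif5bb (-0.77). Intraflagellar transport genes held 3 lower of 16, among them ift57 (-0.86) and ift27 (-0.43, a call lost in 6 of 31 alternative settings), and of the 2 axonemal genes dnal1 fell (-1.72). Dynein genes held 2 higher and 1 lower of 14. The higher ones were the heavy chain gene dync1h1, from 1.12 ± 0.542 to 4.79 ± 1.86 FPKM, and the light chain gene dynll2a (0.92, a call lost in 13 of 32 alternative settings).

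None of these lists but the tubulins passed by camera (adjusted p = 0.112 for spindle and for kinesins, 0.202 for centrosome, 0.281 for microtubule-associated and for dynein, 0.519 for intraflagellar transport). By fry, which tests a list on its own and passed 15 of 26 lists here, all but dynein (adjusted p = 0.131) passed. The fry adjusted p was 0.00448 for tubulins, 0.00181 for spindle, 0.0047 for kinesins, 0.00555 for centrosome, 0.0203 for microtubule-associated and 0.0299 for intraflagellar transport. Over all 193 tested members, 49 were lower in mutant FG follicles (25.4%, against 13.2% of other genes; Fisher's exact p = 8.62e-06) and 11 higher (5.7%, against 10.1%; 0.0398), a test chosen after the data were seen. At an absolute log2 change of at least 1 the excess ended, with 8 lower (Fisher's exact p = 0.409). Of the 49, 12 were also called lower in eggs and 36 lay below 0 there. The tubulin call by camera ended with an FPKM minimum of 5, in a fit of FG follicles alone, and without mutant FG follicle library 2 or wild-type FG follicle library 2 or 3, and tubb5 lost its call without wild-type library 2 or 3 or mutant library 3 or 4. Mutant FG follicle library 2 held 13 FPKM of tuba8l2 and the other mutant ones at most 6.05.

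**Figure D2:**
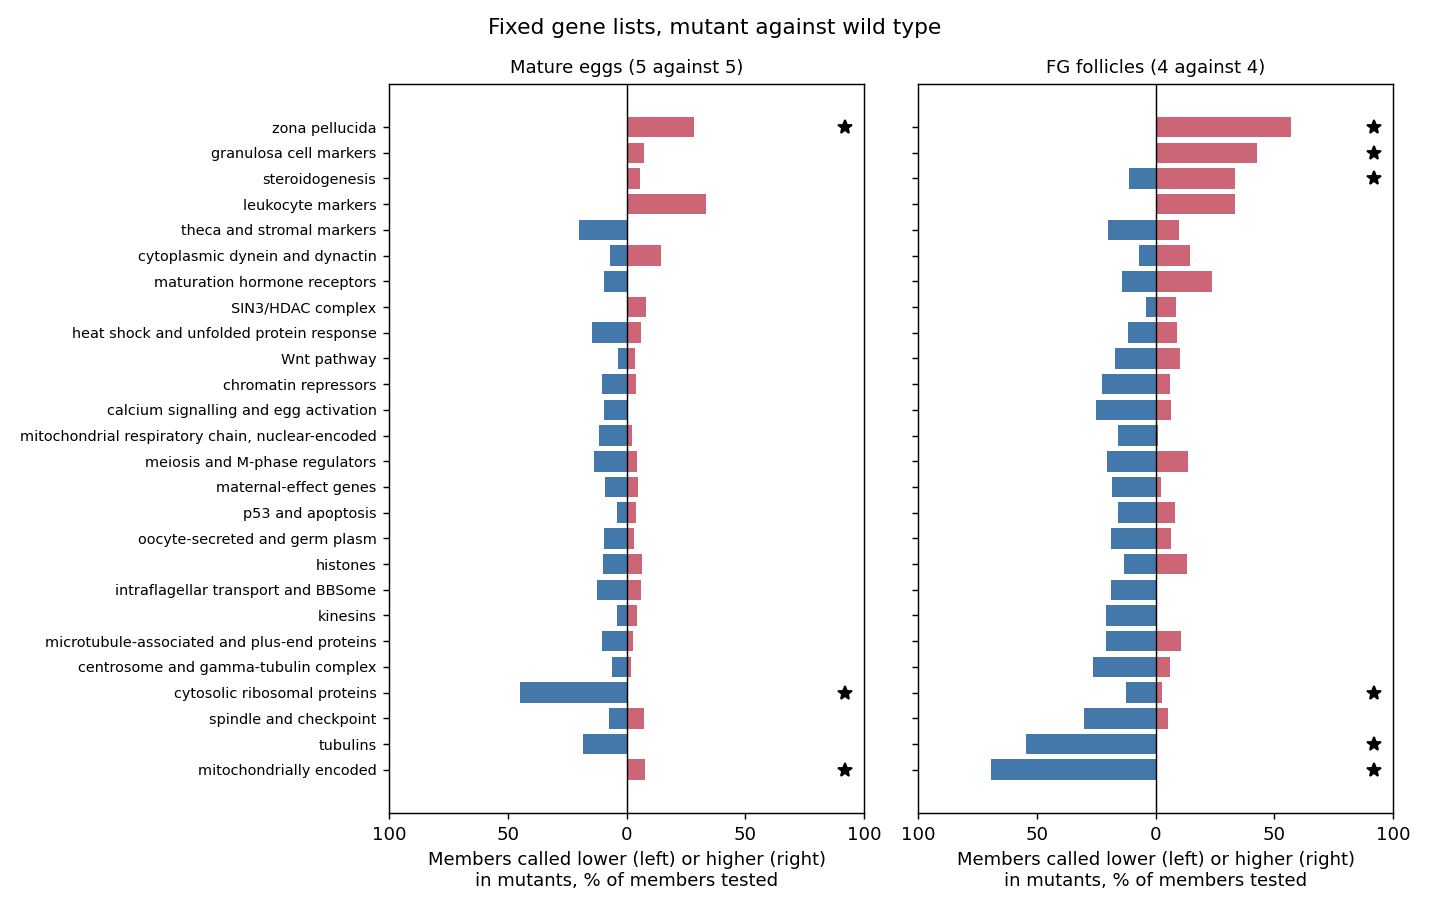
Bars give the percent of tested members of each of 26 fixed gene lists called lower (to the left) or higher (to the right) in mutants by limma, for eggs and for FG follicles, and a star marks a camera adjusted p under 0.05 at the preset correlation, none of which holds with an estimated correlation. Of 80 ribosomal protein genes, 36 were lower in eggs and 10 in FG follicles, and of 14 zona pellucida genes 4 were higher in eggs and 8 in FG follicles.

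Of 14 zona pellucida genes, 8 rose in mutant FG follicles and none fell (9 and 0 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 6.23e-05; adjusted p = 0.563 with an estimated correlation). Beside zp2.5 they included zp3a.1, from 404 ± 115 to 993 ± 95.2 FPKM, zp3b, from 266 ± 85 to 616 ± 66.3 FPKM, and zp2.3, from 26.9 ± 9.39 to 82.3 ± 25.3 FPKM (SD, n = 4 each). Many of these genes are near-identical tandem copies, as are some tubulins and histones, and how shared reads were counted is not stated, so the split among copies is uncertain. Granulosa markers rose in 6 of 14 cases with none lower (7 and 0 adjusted over the list alone), with a median of 0.74 (0.0981 with no filter, where more low genes of the list are tested; camera adjusted p = 0.000144; adjusted p = 0.563 with an estimated correlation). The inhibin subunit gene inha stood at 4.22 ± 3.92 FPKM in wild type and 27.1 ± 25.3 FPKM in mutants (log2 2.11, SE 0.52, limma adjusted p = 0.00638), with 59.0 and 36.1 FPKM in mutant libraries 2 and 4 and 6.45 and 7.00 FPKM in libraries 1 and 3. Wild-type library 1 held 10.1 FPKM of inha, so the groups overlapped. The estradiol-forming enzyme gene hsd17b1 rose from 2.18 ± 0.188 to 9.86 ± 5.99 FPKM and the ovarian transcription factor gene foxl2b from 1.27 ± 0.333 to 3.59 ± 2.32 FPKM (SD, n = 4 each). Of 18 steroidogenesis genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.0175; adjusted p = 0.563 with an estimated correlation). They include hsd17b1 and the nuclear receptor gene nr5a1a (0.92, a call lost in 8 of 31 alternative settings), both also granulosa markers, hsd11b2 (1.59), for which mutant library 2 stood at 56.6 FPKM and the others at most at 18.7, and nr5a2 (0.71, and 0.46 without mutant library 2). The mean granulosa score was 1.24 ± 0.314 in mutants and 0.851 ± 0.101 in wild type (SD, n = 4 each; exact permutation p = 0.0857, adjusted over 12 scores 0.206; with TPM the difference was 0.580 and p 0.0286). The steroidogenesis call ended without mutant FG follicle library 2, with no filter, with an FPKM minimum of 5 and with array weights, and the granulosa call ended with array weights.

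Mitochondrially encoded genes fell in 9 of 13 cases with none higher (0 higher and 13 lower adjusted over the list alone), with a median of -0.70 (camera adjusted p = 0.000144; adjusted p = 0.563 with an estimated correlation). Examples were mt-nd6, from 409 ± 98.4 to 196 ± 42.6 FPKM, mt-atp6, from 6650 ± 1630 to 3420 ± 1110 FPKM, mt-atp8, from 4790 ± 1140 to 2450 ± 476 FPKM, and mt-nd2, from 1260 ± 117 to 725 ± 230 FPKM (SD, n = 4 each). The fall was larger in mutant libraries 1 and 3, where these genes took 8.2 and 7.6% of summed FPKM, than in libraries 2 and 4 (12.3 and 13.8%), against 14 to 17.7% in wild type. Without library 4 the median was -0.86 and without library 3 -0.53 (list mitochondrially encoded: mutant vs wild type, FG follicles). The calls of mt-atp6 and mt-atp8 ended with quantile normalization and that of mt-nd2 with median-of-ratios scaling. Of 80 ribosomal protein genes, 10 fell and 2 rose (3 and 1 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.028; adjusted p = 0.723 with an estimated correlation). The genes rplp2l (-0.83), rpl14 (-0.65) and rps25 (-0.59, a call lost in 7 of 32 alternative settings) fell and rpl12 (0.76) rose. The ribosomal call ended with an FPKM minimum of 5, with median-of-ratios scaling, quantile normalization and TPM, and without mutant FG follicle library 2 or wild-type FG follicle library 2 or 4. As many called lists as in the real split came from 12 of 35 splits of the FG follicle libraries, the real one included, so the 6 list calls are not set apart from other groupings.

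Other FG follicle lists held called members without passing by camera. The protease gene ctsba fell from 1320 ± 53.3 to 435 ± 19.8 FPKM and the syntaxin-binding gene sybu from 102 ± 15.7 to 39.3 ± 4.43 FPKM (a call lost in 12 of 32 alternative settings), among 43 maternal-effect genes with 1 higher and 8 lower (adjusted p = 0.316). With cdc26, from 12.4 ± 1.9 to 0.254 ± 0.249 FPKM, 9 of 44 meiosis genes were lower and 6 higher (0.52). The progesterone receptor gene pgr rose from 1.72 ± 1.11 to 8.57 ± 6.7 FPKM, with 5 higher and 3 lower of 21 hormone receptor genes (0.202). The histone gene hist1h2a11 rose (2.11; 4 higher and 4 lower of 30; 0.732), and zar1l fell (-1.21; 2 higher and 6 lower of 32 oocyte-secreted and germ plasm genes; 0.519). The SIN3 complex list held 2 higher, among them phf12b (0.89), and 1 lower of 24 (0.282), and chromatin repressors, hdac3 included, 3 higher and 11 lower of 49 (0.281). Nuclear respiratory chain genes held 1 higher and 15 lower of 95, with atp5if1a at -0.99 (0.202). Calcium signalling genes held 2 higher and 8 lower of 32, with plcd1b at -0.84 (0.202). The cyclin gene ccng1 fell again (-2; 2 higher and 4 lower of 25 p53 genes; 0.52) and hspa9 rose again (1.26; 3 higher and 4 lower of 34; 0.519). Wnt genes, with sybu among them, held 3 higher and 5 lower of 29 (0.992). The protease inhibitor gene timp2a fell (-1.88) in the theca and stromal list, whose median was 0.19 while its mean (-0.07) and test pointed down (1 higher and 2 lower of 10; 0.989). The antigen presentation gene cd74a rose (0.94, and 0.57 without mutant library 2; 2 higher and 0 lower of 6 leukocyte markers; 0.281), as did the erythrocyte gene cahz (0.73, a call lost in 5 of 31 alternative settings; 1 of 4). Adjusted over the list alone the counts were 6 higher and 3 lower for hormone receptors, 4 and 5 for histones, 3 and 12 for chromatin repressors, 0 and 9 for nuclear respiratory chain genes and 3 and 0 for leukocyte markers. No endothelial (0 of 2) or liver marker (0 of 1) was called. Scores of the cell types other than granulosa differed by 0.066 for theca and stroma (exact permutation p = 0.771), 0.162 for leukocytes (0.371), 0.064 for erythrocytes (0.4), 0.062 for endothelium (0.257) and -0.003 for liver (1), all with an adjusted p of at least 0.514. Without mutant library 2 they were -0.0329 for theca and stroma, 0.0545 for leukocytes, 0.0198 for erythrocytes and 0.0314 for endothelium. Mutant libraries 2 and 4 lay above all wild-type libraries in all 6 scores, granulosa included, and libraries 1 and 3 above them in none.

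**Figure D3:**
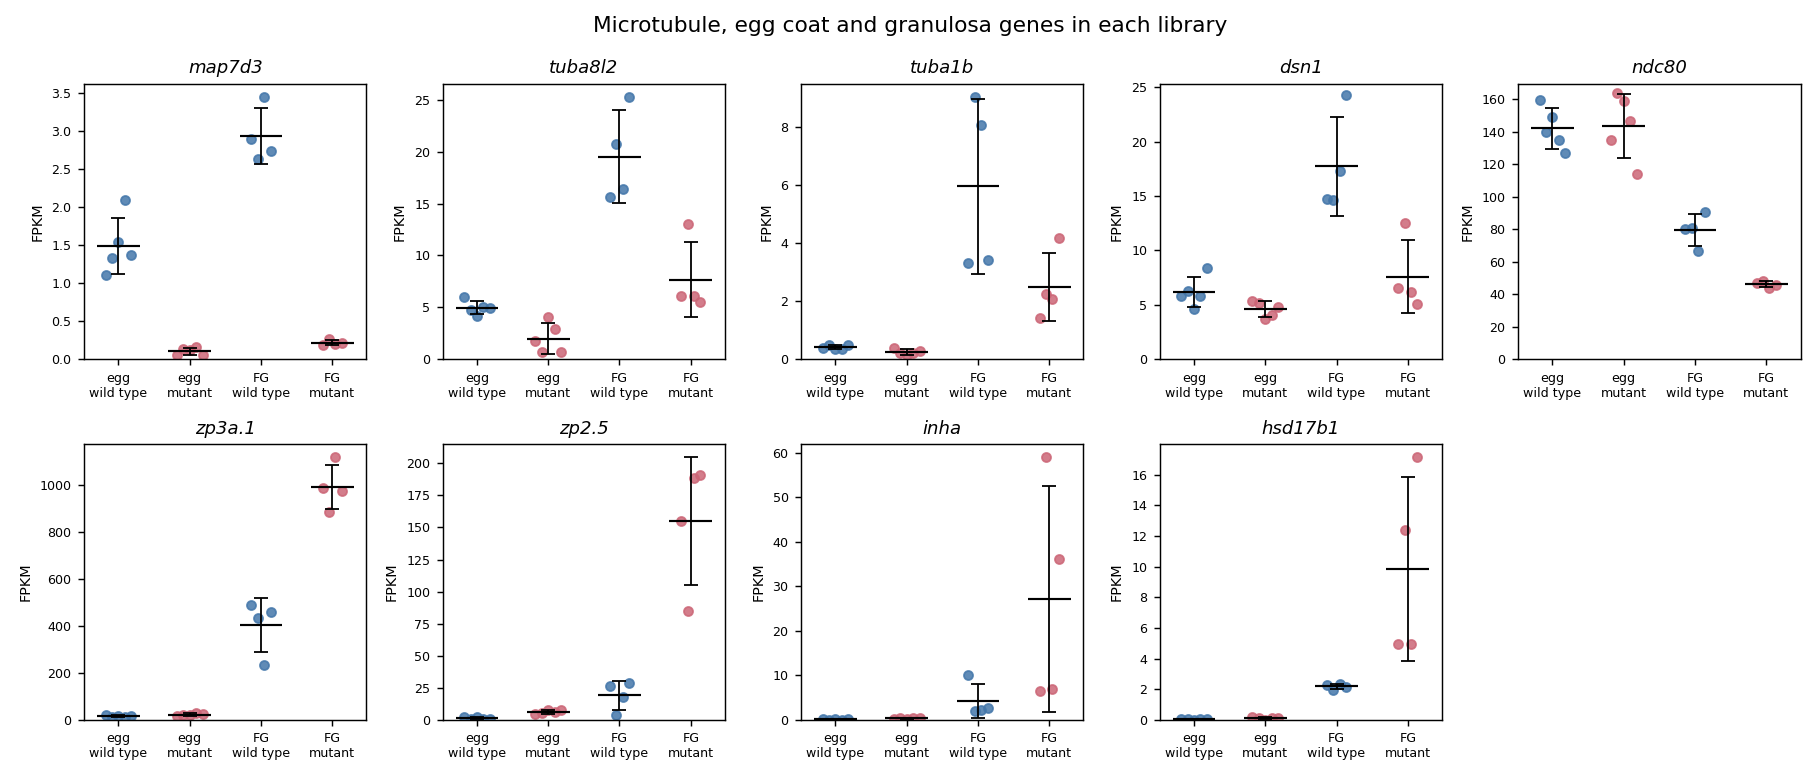
FPKM of 9 genes by stage and genotype, each dot a library, each line a group mean and each bar the SD. In FG follicles map7d3 averages 2.93 in wild type and 0.214 in mutants, zp3a.1 averages 404 and 993, and inha spreads from 6.45 to 59.0 within the mutants.

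The overlap of both genotype comparisons asked whether the same genes change at both stages. Lower in mutant eggs and mutant FG follicles were 441 genes, among them spsb1, sec11a, fancg, mettl2a, cdc26 and map7d3, where 109 would be shared by independent lists (Fisher's exact p = 9.69e-190, odds ratio 10.7). Higher in both were 233 genes, among them prps1b, hdac3, kyat3, gpx8 and hspa9, where 78 would be shared (Fisher's exact p = 7.57e-60, odds ratio 4.64). Of the egg calls, 54.2% of the lower and 30.1% of the higher ones were shared, and 26 genes were called in opposite directions. Log2 changes correlated across genes at 0.60, where genes are not independent replicates. Genes lower at both stages often lay close together on the chromosomes. Of 409 that could be placed, 212 (51.8%) had another within 5 tested genes, against a median of 143 in random sets matched on expression. Genes higher at both stages did so as well, prps1b and hdac3 among them (66 of 203, 32.5%, against a median of 38). The counts of shared genes at an absolute log2 change of at least 1 came to 175 in all.

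The difference of the mutant effect between stages, eggs minus FG follicles, was tested as a contrast of its own. Mitochondrially encoded genes went apart, with 12 of 13 more positive in eggs (13 adjusted over the list alone) and a median difference of 1.15. The largest single differences belonged to nupr1b (4.19), mrpl1 (3.82), arfgap1 (2.96) and foxa (2.95), all but arfgap1 transcripts of wild-type FG follicles that stood below 0.5 FPKM in mutant ones. The foxa transcript, of a forkhead transcription factor, stood at 10.7 ± 2.65 FPKM in wild-type and 0.00699 ± 0.014 FPKM in mutant FG follicles (SD, n = 4 each), and at 0.506 ± 0.22 FPKM in wild-type eggs (SD, n = 5). Mutant egg library 3 held 0.032 FPKM of foxa and the other mutant egg libraries 0, so it was nearly absent from mutants at both stages. Its difference between stages thus follows its low level in wild-type eggs on the log2(FPKM + 1) scale. The gene arfgap1, a regulator of vesicle coats, rose in mutant eggs from 2.72 ± 0.474 to 15.8 ± 2.39 FPKM. It was lower in mutant FG follicles, at 4.94 ± 1.68 FPKM against 9.12 ± 1.51 FPKM in wild type. In all, 733 genes differed by limma, 446 more positive in eggs and 287 more positive in FG follicles, with 190 and 125 by at least 1. The share more positive in eggs was 60.8%, but 40.9% with median-of-ratios scaling and 34% with TPM, and the median gene moved from 0.08 to -0.03 and -0.11, so the balance of directions turns with the scaling. The innate immune gene ptx3b differed by 2.63, spns1 by -2.50, mt2 by -2.43, fancm by -2.07, gemin4 by -2 and ppp2r5ca by -2.08 (adjusted p = 0.0405). For ppp2r5ca, wild-type FG follicle library 2 held 5.44 FPKM and the others at most 0.155, and its call was lost in 23 of 33 alternative settings, 13 of 18 that leave out a library among them. The spns1 difference was -0.49 and not called with a pseudocount of 0.1.

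By camera at its preset correlation 7 lists differed, and none of them with an estimated correlation (adjusted p = 0.828 to 0.896). Without each library in turn the count moved by over 1.5 times in 10 of 18 cases, to 4 or 3. Beside the mitochondrial list (camera adjusted p = 1.57e-09), those that differed were spindle and checkpoint by a median of 0.19 (1 higher and 0 lower; adjusted p = 0.0495), zona pellucida by -0.43 (0 and 0; 0.0283), maturation hormone receptors by -0.25 (0 and 1; 0.0468), steroidogenesis by -0.07 (0 and 1; 0.0495), granulosa markers by -0.61 (0 and 2; 0.000825) and ribosomal proteins by -0.23 (0 and 3; 0.000247). Adjusted over the list alone the counts were 6 higher for spindle, 4 lower for hormone receptors, 3 for steroidogenesis and 2 for granulosa, and 0 for zona pellucida and ribosomal proteins. Over the 193 microtubule list members, 3 were more positive in eggs (Fisher's exact p = 0.0685) and 2 in FG follicles (0.181), so an effect of genotype on these genes at only a single stage was not shown.

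Eggs were set against FG follicles in wild type to give the background difference between both kinds of sample. In eggs transcripts of the egg coat were lower and those of the mitochondrial genome higher. The germ plasm organizer buc stood at 937 ± 37.6 FPKM in FG follicles (SD, n = 4) and 22.1 ± 5.22 FPKM in eggs (SD, n = 5), and the transcription factor gene eomesa at 11 ± 3.09 and 174 ± 7.79 FPKM. By limma 8746 genes differed, 2335 higher and 6411 lower in eggs, with 1327 and 4808 by at least 1. In 8017 genes the groups did not overlap, where chance gives 1.59%. The median gene differed by -0.85, but by -0.13 with median-of-ratios scaling, -0.05 with quantile normalization, -1.32 with TPM and -1.05 with TPM without mitochondrial genes. The share of higher genes was 26.7%, 46.4% with median-of-ratios scaling and 48.8% with quantile normalization, so the excess of lower genes holds on some scales and not on others. The largest rises from FG follicles to eggs were those of the splicing factor gene srsf7a (4.33), papd7 (4.25), map3k1 (3.99), rflnb (3.94) and eomesa (3.90), and the largest falls those of dab2 (-5.43), buc (-5.37), the microtubule-destabilizing stmn1a (-5.35), mrpl17 (-5.19) and neil1 (-5.12). All 14 zona pellucida genes fell (median -3.63; camera adjusted p = 0.00243; adjusted p = 0.487 with an estimated correlation), as did 79 of 95 nuclear respiratory chain genes with 7 higher (-1.86; 0.00067; adjusted p = 0.514 with an estimated correlation). All 13 mitochondrially encoded genes rose (1.74; 5.56e-07; adjusted p = 0.487 with an estimated correlation). Chromatin repressors held 25 higher and 17 lower of 49 (0.39; 0.00016; adjusted p = 0.333 with an estimated correlation), ribosomal proteins 31 and 18 of 80 (0.29; 0.000107; adjusted p = 0.619 with an estimated correlation) and calcium signalling genes 15 and 8 of 32 (0.20; 0.00243; adjusted p = 0.487 with an estimated correlation). Adjusted over the list alone these counts were the same but for respiratory chain genes (80 lower) and ribosomal proteins (17 lower). Granulosa markers held 0 higher and 13 lower of 14, and theca and stromal markers 2 and 8 of 10 (camera adjusted p = 0.241 and 0.837). FG follicles carry follicle cells, so a different make-up of cells and a change within the oocyte cannot be told apart in this comparison.

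The same comparison in mutants gives the counterpart. Again egg coat transcripts were lower in eggs, with zp3a.1 at 993 ± 95.2 FPKM in FG follicles (SD, n = 4) and 21.9 ± 5.08 FPKM in eggs (SD, n = 5) and zp3b at 616 ± 66.3 and 18.7 ± 5.44 FPKM. The mitochondrial gene mt-nd6 stood at 196 ± 42.6 and 3740 ± 964 FPKM. By limma 8615 genes differed, 2471 higher and 6144 lower in eggs, with 1448 and 4687 by at least 1 and 7891 without overlap of groups (1.59% of genes by chance). The median gene differed by -0.79, by -0.13 with median-of-ratios scaling, 0 with quantile normalization, -1.43 with TPM and -0.90 with TPM without mitochondrial genes, and the share of higher genes was 28.7%, 46.3% with median-of-ratios scaling and 49.5% with quantile normalization. The largest rises were those of rflnb (4.65), sh2d5 (4.34), map3k1 (4.26), mt-nd6 (4.23) and znf346 (4.16), and the largest falls those of zp3a.1 (-5.46), crp2 (-5.36), dab2 (-5.29), stmn1a (-5.26) and zp3b (-5.01). By camera 8 lists passed: zona pellucida (0 higher and 14 lower; median -4.11; adjusted p = 0.0011), mitochondrially encoded (13 and 0; 3.02; 3.03e-09), nuclear respiratory chain (8 and 78 of 95; -1.72; 0.000921), chromatin repressors (25 and 15 of 49; 0.39; 0.000467), calcium signalling (15 and 9 of 32; 0.28; 0.00144), kinesins (8 and 7 of 24; 0.12; 0.0272), ribosomal proteins (24 and 25 of 80; 0.019) and maternal-effect genes (19 and 20 of 43; 0.0497). For ribosomal proteins the median was -0.06 and the mean -0.09, and for maternal-effect genes -0.21 and -0.13, while the test, which sets a list against all other genes, pointed up. Counts adjusted over the list alone were the same for all 8. None of the 8 held with an estimated correlation (adjusted p = 0.405 to 0.75 with an estimated correlation). Granulosa markers again held 0 higher and 13 lower of 14 and theca and stromal markers 2 and 8 of 10 (camera adjusted p = 0.0557 and 0.566). The make-up of cells thus cannot be told apart from a change within the oocyte here either.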

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

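Chosen only after their results were seen were the counts of neighbours among genes lower or higher at both stages of any size and among genes lower in FG follicles alone, both tests of a larger share of follicle cells, and the tests on means of a list per library.

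Other groupings of the same libraries were tried for each count of genes. In eggs 1588 genes were called, and 1 of 100 splits, the real one, gave as many, with 1186 the highest of the others. Chance is thus unlikely to give so many. That highest count is among 4 other splits that hold all egg libraries numbered 4 and 5 together and call 0 to 1186 genes, which points to a structure of the egg libraries by number. The 13 other drawn splits that part every same-numbered pair called 0 to 2 genes, while for mutant vs wild type, mature eggs, libraries 1 to 3 alone called 1311 genes and libraries 4 and 5 alone 1174. In FG follicles 2475 genes were called, 1 of 35 splits, the real one, gave as many and the highest other gave 79. No smaller share is possible with 35 splits, so chance is unlikely there and not excluded. In each comparison the other splits mix the compared groups, so a real difference widens their spread and lowers their counts. For the difference between stages, 733 genes were called and 4 of 100 splits, the real one included, gave as many. The 3 others called 1637, 829 and 747 genes. They kept 2 of 10 egg and 8 of 8 FG follicle labels, 0 and 6, and 6 and 0, so they come near to turning the labels of a whole stage, which adds the effects of both stages where the contrast subtracts them. These splits shuffle genotype within each stage and so break the genotype effect at both stages. They cannot decide whether the calls of a difference between stages exceed chance. For eggs against FG follicles, 1 of 100 splits gave as many genes in wild type (8746, highest other 7986) and 1 of 100 in mutants (8615, highest other 7974), the real split each time. For the fixed lists, other splits often gave as many. In eggs 43 of 100 splits called at least the real 3 lists (highest other 5), and in FG follicles 12 of 35 called at least the real 6 (highest other 9). List by list, a camera p as small came from 17 of 100 splits for zona pellucida, 31 for ribosomal proteins and 42 for mitochondrially encoded genes in eggs. In FG follicles it came from 4 of 35 splits for zona pellucida, 13 for tubulins, 12 for steroidogenesis, 14 for granulosa markers, 18 for ribosomal proteins and 10 for mitochondrially encoded genes.

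The first pattern is the 33 genes lower in mutants at both stages by at least 2 on the log2 scale, among them spsb1, spns1, sec11a and cdc26. A haplotype carried along with the sinhcaf mutation is excluded as the whole cause, since 0 of the 30 that could be placed lie among the 100 nearest tested genes on each side of sinhcaf. Blocks of different genetic background between mutant and wild-type fish remain a candidate explanation, since 19 of the 30 have another of them within 5 tested genes (median 0 and at most 10 in 10000 random sets matched on expression), all 19 on 3 chromosomes, with spsb1, gpr157, clcnk, szrd1 and atp13a2 close together. Genes of any size lower at both stages lie close as well (212 of 409, 51.8%, against 35% in random sets), and so do those higher at both (66 of 203, 32.5%, against 18.7%, at most 65 in random sets), with prps1b and hdac3 as near neighbours among the 9 placed that rose by at least 2, so background stays open for rises too. For genes lower in FG follicles and not in eggs (555 of 881, 63%, against 61.5%, 95th percentile 567 and at most 598 in random sets), the count was at the level of random sets. Most genes of a random set of that size have a neighbour too, and genes called at both stages are left out, so blocks are neither shown nor excluded there. An effect of sinhcaf itself was not tested apart from background, as the labels say nothing of how the mutant and wild-type fish are related.

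The second pattern is the rise of granulosa markers and zona pellucida genes in mutant FG follicles. A larger share of follicle cells is excluded for the zona pellucida part, since these are genes of the oocyte, their median is 0.82 (95% bootstrap interval 0.41 to 1.27, resampling the 14 genes and not the fish), and their mean per library was higher in all 4 mutant libraries than in all 4 wild-type ones (difference 0.92, exact permutation p = 0.0286, the smallest possible). For the granulosa part, the granulosa score minus the theca and stromal score was higher in all 4 mutant libraries than in all 4 wild-type ones (difference 0.32, exact permutation p = 0.0286, the smallest possible). This does not exclude a like rise of all follicle cells. In mutant libraries 1 and 3 the difference rests on low theca and stromal scores (0.865 and 0.874, against at least 0.933 in wild type). In libraries 2 and 4, where granulosa markers rose, the theca and stromal scores rose too. More granulosa cells alone, or more transcripts in each, stay open as well. An earlier point of collection cannot be told apart from a genotype effect, since the mutant effect correlates across genes with the step from FG follicles to eggs at -0.126 at the lowest and -0.07 at the highest of 6 assignments of wild-type libraries, above -0.2 in all and on both sides of -0.1, the bounds set beforehand. On the first principal component all 4 mutant FG follicle libraries (102.24 to 105.74) lay farther from eggs than all 4 wild-type ones (91.46 to 99.58). That does not decide between them either. An effect of genotype on the follicle stays open as untested, and so does a larger share of other cells in mutant libraries 2 and 4 alone, which lie above all wild-type libraries for granulosa (1.62 and 1.37), theca and stromal (1.438 and 1.386), leukocyte (0.979 and 0.714), erythrocyte (0.594 and 0.564) and endothelial markers (0.509 and 0.459), while the granulosa scores of libraries 1 and 3 (0.979 and 0.981) lie inside the wild-type range of 0.771 to 0.992.

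The third pattern is the fall of ribosomal protein transcripts in mutant eggs, with a median of -0.49 (95% bootstrap interval -0.55 to -0.41, here and below resampling genes and not fish). A larger mitochondrial share of the library is excluded as the whole cause, since after rescaling without mitochondrially encoded genes the median was still -0.40 (-0.46 to -0.32) and the mean per library differed by -0.33 (n = 5 each, exact permutation p = 0.0238). Egg libraries 1 to 3 and 4 and 5 stand in both genotypes alike, so their split by number could not by itself part the genotypes. The median was -0.30 (-0.37 to -0.20) within libraries 1 to 3 and -0.78 (-0.84 to -0.60) within libraries 4 and 5. All mutant libraries lay below all wild-type ones in each set, where n is too small for a test to pass. Chance is not excluded for the list call, and the sets differ in size of effect. A genotype effect, a difference of background and a difference in RNA handling that went with genotype all stay open, the last of which no label records.

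Single libraries stood apart from the others of their group, by the gap to the nearest divided by the range, in 30 of 360 groups tested, where 1 in 20, or 18, would by chance. In wild-type eggs they were library 5 for lsm12a (gap 0.979), fgd4b (0.914) and rpsa (0.757), library 4 for rnf141 (0.716) and gemin4 (0.763), library 3 for pigl (0.744) and cldn5b (0.792), library 2 for mt2 (0.776) and eomesa (0.8) and library 1 for mrpl17 (0.771). In mutant eggs they were library 1 for kif1bp (0.795) and ptx3b (1) and library 3 for foxa (1), where ptx3b and foxa had no more than 0.0475 FPKM in that library and 0 in the others. In wild-type FG follicles they were library 1 for inha (0.93), atp5if1a (0.875) and the liver score (0.873), library 2 for ppp2r5ca (0.99) and kif26ab (0.844), library 3 for prps1b (0.874) and eomesa (0.876) and library 4 for sde2 (0.966). In mutant FG follicles, library 2 stood apart for mettl2a (0.961), arfgap1 (0.837), tuba8l2 (0.93), hsd11b2 (0.871), hspa9 (0.869) and the number of genes at an FPKM of at least 1 (0.853), library 4 for kansl2 (0.995) and gpr157 (1) and library 1 for foxa (1).

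Of 104 genes named in the genotype comparisons, 30 had a mutant effect that differed between stages by the limma contrast of eggs minus FG follicles, in log2, and 5 more (arfgap1, foxa, ptx3b, ppp2r5ca and fancm) were named because they differ. More positive in eggs were nupr1b (4.19), mrpl1 (3.82), arfgap1 (2.96), foxa (2.95), ptx3b (2.63), rhogd (2.22), abcb10 (1.63), cxcr4b (1.43), mt-nd6 (1.43), mt-atp6 (1.34), ehd1a (1.3), mt-nd2 (1.15), timp2a (1.13), mt-nd5 (1.12), mt-atp8 (1), mrps22 (0.86), cdc26 (0.82), plcd1b (0.82), ndc80 (0.77), fgd4b (0.53) and map7d3 (0.53). More positive in FG follicles were spns1 (-2.50), mt2 (-2.43), hist1h2a11 (-2.40), ppp2r5ca (-2.08), fancm (-2.07), gemin4 (-2), hsd17b1 (-1.52), urahb (-1.44), dync1h1 (-1.38), spsb1 (-1.10), rnf41 (-1.09), fancg (-0.90), sox5 (-0.69) and fn1a (-0.62). These differences are on the log2(FPKM + 1) scale, where the fall of a gene near 0 FPKM in mutants is bounded by its wild-type level. As ratios of mean FPKM, map7d3 fell alike at both stages. By that measure cdc26 fell more in eggs and spsb1 more in FG follicles, the reverse of the order given here. By camera 7 lists differed, in their median by 1.15 (mitochondrially encoded), 0.19 (spindle and checkpoint), -0.61 (granulosa markers), -0.43 (zona pellucida), -0.25 (maturation hormone receptors), -0.23 (ribosomal proteins) and -0.07 (steroidogenesis), none of them with an estimated correlation.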

How the results depend on the processing

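Settings added after the data were seen were the block nested in stage, the separate sets of egg libraries, the averaged mutant FG follicle libraries 1 and 3 and the pooled microtubule count, and all other settings were chosen beforehand. A count model was not run, as no counts were at hand. Of 155 results for single named genes, 4871 of 5059 values kept direction and side of the threshold, 188 kept direction and lost the call, and 0 reversed. Some settings leave out a library of a group outside the comparison, which cannot change the log2 change. The genes of largest change in each genotype comparison were also chosen for groups that do not overlap. These counts, and those given with single genes, thus overstate stability. The averaged FG follicle libraries were not applied to single genes. Depth is unknown, so what it limits cannot be said.

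Counts of called genes moved by over 1.5 times as follows, for mutant vs wild type, mature eggs (1588), mutant vs wild type, FG follicles (2475), the difference of the mutant effect between stages (733) and the overlap of mutant effects between stages (674). With array weights they were 2573 in eggs, 4232 in FG follicles, 2379 for the difference between stages and 1089 in the overlap. With no filter FG follicles gave 3753, and with an FPKM minimum of 5 they gave 1551 and the difference 394, where more and fewer genes were tested. The difference gave 372 with a pseudocount of 0.1, 473 with TPM and 469 with TPM without mitochondrial genes, and the cause was not tested. A minimum log2 change of 1 left, by its construction, 409 in eggs, 601 in FG follicles, 315 for the difference, 175 in the overlap and 8 lower microtubule members of 49 in FG follicles (Fisher's exact p = 0.409; 1.84e-07 to 0.409 over all settings). Of the 1588 egg calls 996 were kept in egg libraries 1 to 3 and 832 in libraries 4 and 5. With mutant FG follicle libraries 1 and 3 averaged, 1944 of the 2475 FG follicle calls were kept. Leaving out mutant library 1 kept 1949 and leaving out library 3 kept 1919. That libraries 1 and 3 differ by more than counting allows does not settle whether they come from different fish. Without each library in turn no count of genes moved by over 1.5 times.

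Counts of called lists depended most on the test. With an estimated correlation they were 0 in eggs, 0 in FG follicles, 0 for the difference, 0 for the stage comparison in wild type and 0 in mutants, where the unadjusted p was under 0.05 for 0, 2, 1, 1 and 2 lists. With fry, which asks whether a list moves at all, they were 15 in FG follicles, 23 for the stage comparison in wild type, 20 in mutants and 3 for the difference. In eggs 1 list of 3 was left with median-of-ratios scaling, 1 with quantile normalization, 1 with TPM without mitochondrial genes and 1 in libraries 1 to 3. In FG follicles 2 of 6 were left with an FPKM minimum of 5, which gave 11 in place of 6 for the stage comparison in wild type. For the difference, 7 became 4 with no filter, 3 with an FPKM minimum of 5, 4 with quantile normalization, 2 with array weights, 3 in egg libraries 1 to 3 and 3 in libraries 4 and 5. Without each library in turn, list counts ran from 1 to 3 in eggs (1 without wild-type library 4 or 5), 3 to 7 in FG follicles (3 without mutant library 2) and 3 to 7 for the difference (3 without wild-type FG follicle library 3, and over 1.5 times lower without 10 of 18 libraries). For single lists the range of camera adjusted p reached 0.85 in eggs and 0.723 in FG follicles, and every list called in either genotype comparison kept its direction under every setting. For these changes of list counts the cause was not tested. The median of granulosa markers in FG follicles ran from 0.0981 (no filter) to 1.0517, of tubulins there from -0.6671 to -0.2013, and of mitochondrially encoded genes in eggs from 0.0283 (quantile normalization) to 0.5151. Lists not called there, and lists called only in the other contrasts, were not followed one by one.

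Scores for other cell types: erythrocyte markers: egg lost their raw exact p under 0.05 with a pseudocount of 0.1 (0.0754), median-of-ratios scaling (0.0221), quantile normalization (0.0207), TPM (0.0343), in libraries 1 to 3 (0.0281) and without wild-type library 2 or 4 (0.0242 to 0.0408 without any single library). In other cell types: granulosa cell markers: FG the score passed with TPM (0.5802, exact p = 0.0286). The cause was not tested. In egg libraries 1 to 3, where an exact p cannot go below 0.1, the difference was -0.3259 for sinhcaf level: egg, 0.0719 for other cell types: granulosa cell markers: egg, -0.0809 for other cell types: theca and stromal markers: egg and 0.1067 for other cell types: leukocyte markers: egg, all in the same direction as before. The sinhcaf difference in FG follicles ran from -1.1908 (exact p = 0.0286) to -0.7486 without single libraries.

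Scores that passed no test changed sign, and the cause was not tested. For other cell types: endothelial markers: egg they went to -0.0422 and -0.0043 with pseudocounts of 0.1 and 0.5, -0.0155 with median-of-ratios scaling, -0.0294 with quantile normalization, -0.0243 with TPM and -6e-04 with TPM without mitochondrial genes. For other cell types: liver-secreted and vitellogenins: egg they went to -0.0012 with a pseudocount of 0.1, -0.0016 with median-of-ratios scaling, -0.0033 with quantile normalization, -0.0016 with TPM, -0.0029 in libraries 1 to 3 and -0.0018 to 0.0024 without single libraries. For other cell types: liver-secreted and vitellogenins: FG they went to 0.0039 with median-of-ratios scaling, 0.0074 with mutant libraries 1 and 3 averaged and -0.019 to 0.0101 without single libraries. Theca and stromal markers in FG follicles ran from -0.0329 (without mutant library 2) to 0.1582, and were also reversed without mutant library 4.

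With the replicate number as a block, 1721 genes were called for mutant vs wild type, mature eggs, 2546 for mutant vs wild type, FG follicles and 747 for the difference of the mutant effect between stages, and 1948, 2772 and 856 with the block nested in stage. No called list of either genotype comparison was lost and no count of genes moved by over 1.5 times. The limma adjusted p of sinhcaf was 0.25 in eggs and 0.0233 in FG follicles with the block. Among named genes only zp2.1 in eggs lost its call with the block, and only nr5a1a in FG follicles with the nested block.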

Other observations

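The Gene Ontology terms below were chosen after the data were seen and were tested by one-sided Fisher's exact test on called genes (770 terms, 9254 genes). The test treats genes as independent, and other splits of the libraries were not tried for terms.

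Genes higher in mutant FG follicles were enriched for 11 terms. They include extracellular region (30 of 107 genes, 10.7 expected, adjusted p = 8.21e-05), carbohydrate binding (19 of 54, 0.000199), negative regulation of endopeptidase activity (13 of 34, 0.00298), endopeptidase inhibitor activity (7 of 11, 0.00435), extracellular matrix (7 of 13, 0.0112), egg coat formation (6 of 10, 0.0112) and steroid hormone receptor activity (9 of 26, 0.0439). Genes lower there were enriched for 1 term, microtubule (22 of 69, 9.3 expected, 0.0446). Related terms did not pass, among them microtubule-based process (7 of 21, adjusted p = 0.55), centrosome (13 of 56, 0.722) and microtubule binding (18 of 88, 0.722). The term holds genes of the kind the series title names, so it is not independent evidence of direction. Genes lower in mutant eggs were enriched for 7 terms, among them ribosome (43 of 138, 4.21e-13), translation (47 of 196, 3.4e-10) and regulation of cell cycle (13 of 50, 0.0103). The fixed list of ribosomal proteins did not pass in eggs with an estimated correlation of 0.409 between genes (camera adjusted p = 0.85). For that list 31 of 100 splits gave as small a camera p, so the small p of the ribosome terms overstates the evidence. Genes higher in mutant eggs were enriched for 0 terms (lowest Fisher's exact p = 0.00519, carbohydrate binding, 10 of 54, adjusted p = 1).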
